A study of Drosophila melanogaster with 8 samples.

How the data were processed

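Poly(A) RNA from Drosophila heads was measured in 8 libraries, 2 for each combination of genotype (wild type, whose label gives the strain w1118, and the vri allele vriΔ679, written vri679 here) and time (ZT2, in the light, and ZT14, in the dark). The labels state a 12 h light and 12 h dark cycle at 25 °C, entrainment for 3 days, collection on the next day, TRIzol extraction, DNase treatment, a stranded library kit, and 75 nt single-end reads from 4 libraries to a run. They do not state which libraries shared a run. Nothing states that replicates came from separate cultures or fly samples, so every p-value measures the spread between these samples.

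For each library the authors deposited a table of 35411 RefSeq transcripts under 16727 gene symbols, with FPKM and coverage columns. Per the file headers, the values tested here are FPKM, and the second signal column is per-base coverage, used here only for read depth and for one alternative fit. The submitters' processing notes name STAR 2.6.1d, StringTie and the dm6 genome, but no strand setting for counting, so values of genes whose exons overlap another gene are uncertain. No test result from the study was used here. Coordinates are those of the tables, on dm6. The reference annotation was Ensembl BDGP6.54 release 115, in which 19 of 20 genes within 50 kb of vri had the same coordinates as in the tables. RefSeq accessions matched a current symbol for 93.2 % of transcripts, and 25 symbols lay on 2 chromosomes, for which no coordinates are given.

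Coverage over FPKM was constant within each library and gave, for 75 nt reads, 49.3 to 65.4 M mapped reads, of which 47.1 to 62.0 M lay on listed transcripts. At that depth 3 reads on a 3 kb transcript equal 0.0153 to 0.0203 FPKM. Replicates correlated across genes on the log2 scale at r = 0.985 (wild-type ZT2), 0.987 (wild-type ZT14), 0.979 (vri679 ZT2) and 0.967 (vri679 ZT14). The spread between replicates, relative to counting noise alone, gave a chi-square per degree of freedom of 83.6, 74.9, 94.2 and 293.9 in the same order, so counting noise was a small part of it.

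Transcript FPKM was summed per gene symbol. Libraries were scaled by the median of ratios over 12078 genes, with factors of 0.968 to 1.038. Genes with FPKM of at least 1 in at least 2 libraries were tested, 10122 in all, which held 99.86 % of the listed FPKM. All levels in the text are scaled FPKM. One limma 3.58.1 fit (R 4.3.3, statmod 1.5.0) of the 4 groups on log2(scaled FPKM + 0.5), with eBayes trend and robust options, gave 6 comparisons: genotype at ZT2, genotype at ZT14, the mean of both genotype differences, time (ZT14 minus ZT2) in each genotype, and genotype by time (the time difference in vri679 minus that in wild type). P-values were adjusted by Benjamini-Hochberg over all genes tested within a comparison, with 0.05 as the threshold. The fit gave all 4 groups the same spread per gene, although replicates differed most in vri679 ZT14. P-values that compare this group with a single other group can therefore be too small, and those without it too large. Differences are log2 values with the standard error (SE) of the fit, and group levels are means ± SD with n = 2. vri transcripts were tested in the same way with each of 18982 transcripts as the feature.

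Before any value was seen, 33 gene lists were fixed, and 30 had enough genes tested for camera with its preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were the alternatives. Counts of members called are given over all genes tested and, in square brackets, adjusted over the list alone. Genes to name were also chosen by rule beforehand: 14 genes of the circadian clock and its outputs, vri among them, in every comparison, per comparison up to 8 called genes with the largest rise and 8 with the largest fall whose groups of libraries did not overlap (genotype by time without the overlap condition), up to 4 members of each list with the smallest p, and genes within 50 kb of vri. The text names those of them whose calls held in every setting, or gives the library that ends the call.

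On simulated data with spread taken from these libraries, the fit was tested on 100 genes changed 2-fold and 100 changed 4-fold. It recovered 79 and 96 for genotype at ZT2, 75 and 94 for genotype at ZT14, and 21 and 87 for genotype by time. False calls made up 2.3 to 7 % of calls. The simulation gave every group the same spread and drew genes independently. These shares and recoveries therefore do not cover the larger spread between the vri679 ZT14 replicates.

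The alternative settings chosen before any value was seen were transcripts as features, FPKM of at least 5 or no filter, no rescaling, rescaling to equal totals, quantile normalization, pseudocounts of 0.1 and 1, eBayes without trend and robust options, only the groups compared, the replicate number as a block, and each library left out in turn. Fits that leave out a library assume that the lone sample left in its group varies like the samples of other groups. Chosen after the data were seen were limma-voom on reads estimated from coverage, vri summed by first exon, the list counts without each vri679 ZT14 library, lists of antennal and palp receptor genes, and the tests under the closing section. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.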

Results

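Head transcriptomes of wild-type and vri679 flies were compared at ZT2 and ZT14, with 2 libraries in each of 4 groups. Mapped reads were 62.6 and 53.5 M (wild-type ZT2, replicates 1 and 2), 65.4 and 58.4 M (wild-type ZT14), 61.1 and 49.3 M (vri679 ZT2), and 56.4 and 59.7 M (vri679 ZT14). Between 9631 and 9893 genes reached 1 FPKM in a library. The genotypes differed at white (w) as well as at vri, and nothing states that the stocks share a background, so the genotype comparisons do not separate vri from other differences between the stocks. The tests of vri by first exon, the voom fit and the list counts without each vri679 ZT14 library were chosen after the data were seen; all other tests in this part were fixed beforehand.

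The first question was how vri transcripts differ in vri679 (2L 5288944–5311223, plus strand). Transcripts RA, RD and RF share the first exon at 5305650–5306166 and encode a long protein of 729 amino acids. RE starts at 5288944 and RC at 5299647, and both encode a short protein of 610 amino acids. Long transcripts stood at 9.66 and 10.7 FPKM in the wild-type ZT2 libraries and at 82.8 and 71.9 in the wild-type ZT14 libraries. In vri679 they stood at 0.0183 and 0.0118 at ZT2 and at 0.218 in ZT14 replicate 1, but at 30.1 in the library labelled vri679 ZT14 replicate 2. Short transcripts stood at 0.451 and 0.0444, then 3.05 and 0.71, in wild type, and at 3.62 and 4.27, then 21.6 and 10.5, in vri679. The long form made up 95.5 to 99.6 % of vri FPKM in wild type, 0.3 to 1 % in 3 vri679 libraries, and 74.1 % in the library labelled vri679 ZT14 replicate 2.

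The pseudocount of 0.5 FPKM lies above the long form's level in 3 vri679 libraries, so its log2 differences are bounded by that offset and understate the ratio of levels. By first exon, the log2 difference of long transcripts between genotypes was −4.37 (SE 1.66, adjusted p = 0.497) at ZT2 and −4.05 (SE 1.66, adjusted p = 0.23) at ZT14. Without the library labelled vri679 ZT14 replicate 2, these were −4.37 (SE 0.14, adjusted p = 0.00371) and −6.76 (SE 0.17, adjusted p = 0.000675). Without vri679 ZT14 replicate 1 they were −4.37 (adjusted p = 0.00312) and −1.35 (adjusted p = 0.0262). Short transcripts differed by 2.62 (SE 0.64, adjusted p = 0.258) at ZT2 and 2.91 (SE 0.64, adjusted p = 0.076) at ZT14, the latter 3.41 (adjusted p = 0.0496) without the library labelled vri679 ZT14 replicate 2. As single transcripts, vri-RE, which carries nearly all short-form signal, gave the same 2 differences, and vri-RD fell by 4.20 (SE 0.49, adjusted p = 0.0396) at ZT2 and by 6.13 (SE 0.49, adjusted p = 0.00505) at ZT14. The ZT2 call of vri-RD was lost without any wild-type library or either vri679 ZT2 library, with differences of −4.26 to −4.15. vri-RA and vri-RF were not called: vri-RA differed by −1.40 (SE 1.88, adjusted p = 0.904) at ZT2 and −1.90 (SE 1.88, adjusted p = 0.57) at ZT14. RD ends at 5310610, whereas RA ends with RE at 5310996. In deposited FPKM, RD stood at 8.16, 8.98, 50.1 and 63.0 in the wild-type libraries and RA at 0.757, 0.857, 27.1 and 5.99, while the library labelled vri679 ZT14 replicate 2 had 0.932 of RD and 27.6 of RA. StringTie's division of reads among RA, RD and RF is uncertain, because these share most of their sequence.

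**Figure D1:**
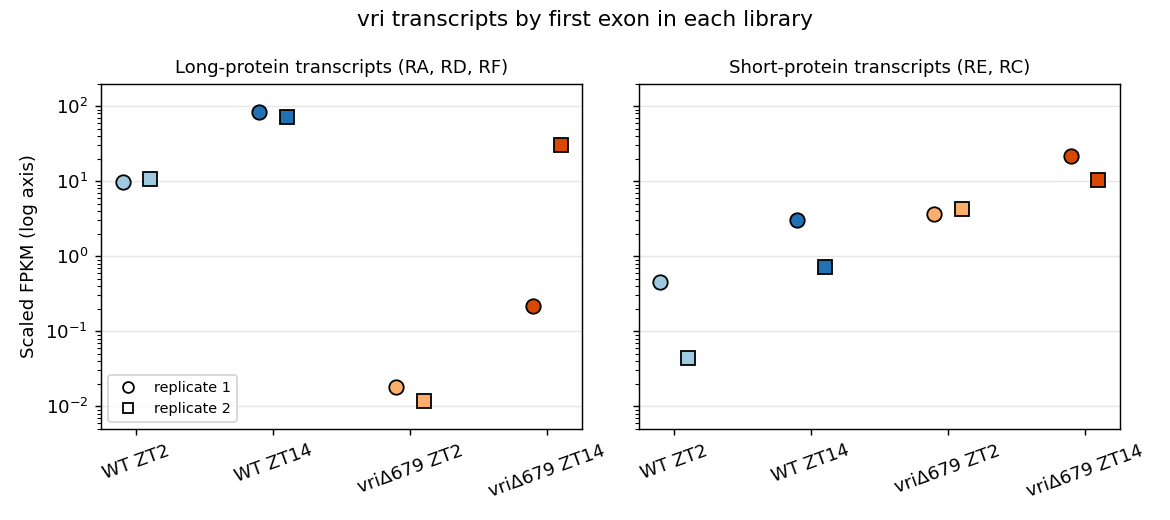
Scaled FPKM of long-protein (RA, RD, RF) and short-protein (RE, RC) vri transcripts in each library, on a log axis. Circles are replicate 1 and squares replicate 2.

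Summed over all transcripts, vri stood at 10.4 ± 0.425 (wild-type ZT2), 79.3 ± 9.37 (wild-type ZT14), 3.96 ± 0.458 (vri679 ZT2) and 31.2 ± 13.3 FPKM (vri679 ZT14). Averaged over both times, vri was lower in the mutant, by −1.34 (SE 0.19, adjusted p = 0.00721). The difference was −1.39 (SE 0.27, adjusted p = 0.0145) at ZT14, where the call was lost without wild-type ZT14 replicate 1 (adjusted p = 0.0938) or replicate 2 (adjusted p = 0.0682). At ZT2 it was −1.29 (SE 0.27, adjusted p = 0.0618), called without either vri679 ZT14 library (adjusted p = 0.00503 each). From ZT2 to ZT14 vri rose in both genotypes, by 2.87 (SE 0.27, adjusted p = 0.00226) in wild type and 2.77 (SE 0.27, adjusted p = 0.00324) in vri679. In vri679 ZT14, replicate 1 had 21.8 FPKM and the library labelled replicate 2 had 40.6, of which 30.1 was the long form. The size of the vri679 rise thus depends on the latter library. With 1 library left out, the genotype by time difference of vri ranged over −0.54 to 0.34. Of the other tested genes within 50 kb of vri, CG14022 (2L 5327975–5328879) was higher in the mutant by 0.96 on average (SE 0.13, adjusted p = 0.00591), at 29.3 ± 2.09 and 23.9 ± 0.45 FPKM in wild type and 52.9 ± 1.39 and 51.9 ± 13.9 in vri679.

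The next question was whether clock transcripts differed between ZT2 and ZT14 in wild-type heads. Among genes with evening E-box control, per (X 2685580–2692780) rose by 2.07 (SE 0.20, adjusted p = 0.00262), from 8.70 ± 1.37 to 38.4 ± 8.91 FPKM, and tim (2L 3493986–3508119) by 2.93 (SE 0.18, adjusted p = 0.000446), from 20.9 ± 1.48 to 163 ± 29.7. Clk (3L 7763233–7775603) fell by 1.44 (SE 0.15, adjusted p = 0.00375), from 10.5 ± 0.301 to 3.56 ± 0.0252, and cry (3R 19212154–19215442) by 1.30 (SE 0.14, adjusted p = 0.00361), from 164 ± 6.09 to 66.6 ± 2.99. The output genes to (3R 25240180–25241668), a juvenile hormone binding family member, and Ugt35b fell by 2.15 (SE 0.25, adjusted p = 0.00497) and 2.18 (SE 0.22, adjusted p = 0.00298). cwo rose by 1.07 (SE 0.21, adjusted p = 0.0309), a call kept only when a vri679 ZT14 library was the one left out (other 6 libraries: adjusted p = 0.063 to 0.173), and Pdp1 differed by 0.65 (SE 0.20, adjusted p = 0.123), called without vri679 ZT14 replicate 1 (adjusted p = 0.00745) or the library labelled vri679 ZT14 replicate 2 (adjusted p = 0.00743). The list of per, tim, vri, Pdp1 and cwo rose with a median of 2.07, 4 members called [5 over the list alone] (camera adjusted p = 5.24e-07; adjusted p = 0.521 with an estimated correlation). The per and tim values carry the limit that exons of both genes overlap another gene.

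The same clock genes were then compared within vri679. per rose by 3.75 (SE 0.20, adjusted p = 0.000406), from 6.14 ± 0.92 to 88.3 ± 9.09 FPKM, and tim by 3.28 (SE 0.18, adjusted p = 0.000406), from 25.9 ± 2.39 to 258 ± 43.9. Clk fell by 0.92 (SE 0.15, adjusted p = 0.0163), from 14.1 ± 0.691 to 7.29 ± 1.62, a call lost without vri679 ZT2 replicate 1 (adjusted p = 0.0752) or replicate 2 (adjusted p = 0.0945). Ugt35b fell by 1.38 (SE 0.22, adjusted p = 0.0141), lost without the same replicate 1 (adjusted p = 0.0832) or replicate 2 (adjusted p = 0.0597). The evening list rose here too, with a median of 2.77 and 5 members called [5], 3 without either vri679 ZT2 library, with only the groups compared or with equal totals (camera adjusted p = 2.47e-06; adjusted p = 0.396 with an estimated correlation).

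Between genotypes, some clock genes differed at ZT14. The output gene to was higher in vri679 by 1.75 (SE 0.25, adjusted p = 0.00515), at 36.8 ± 10.6 against 10.4 ± 1.14 FPKM. per was higher by 1.21 (SE 0.20, adjusted p = 0.00862), and by 0.97 (adjusted p = 0.0615) without wild-type ZT14 replicate 2. Clk was higher by 0.92 (SE 0.15, adjusted p = 0.00841), a call lost without wild-type ZT14 replicate 1 (adjusted p = 0.0562) or replicate 2 (adjusted p = 0.0653). tim was higher by 0.66 (SE 0.18, adjusted p = 0.0413), a call kept only when vri679 ZT14 replicate 1 was the library left out (other 7 libraries: adjusted p = 0.0645 to 0.212). The output list had a median of 0.65 and 5 of 7 members higher [5], 1 without wild-type ZT14 replicate 1 or replicate 2 or with only the groups compared, and 3 with equal totals (camera adjusted p = 0.00743, and 0.0504 without the library labelled vri679 ZT14 replicate 2; adjusted p = 0.36 with an estimated correlation). The evening list, which includes the mutated gene vri itself, did not pass (median 0.41, camera adjusted p = 0.241). Of its 5 genes, per and tim were called higher and vri lower. The other core clock genes did not pass either (median −0.11, camera adjusted p = 0.596). Of the latter 15 genes, 1 was higher [2] and 3 lower [3]; 1 was lower without wild-type ZT14 replicate 2, and 2 were higher and 6 lower without the library labelled vri679 ZT14 replicate 2. cry differed by 0.41 (SE 0.14, adjusted p = 0.0725), called without vri679 ZT14 replicate 1 (adjusted p = 0.0282).

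At ZT2 no gene of the evening and morning clock lists was called between genotypes: per differed by −0.47 (SE 0.20, adjusted p = 0.361), tim by 0.30 (SE 0.18, adjusted p = 0.526), Clk by 0.40 (SE 0.15, adjusted p = 0.301) and cry by −0.18 (SE 0.14, adjusted p = 0.625). Clk was called without vri679 ZT14 replicate 1 (adjusted p = 0.0399) or without the library labelled vri679 ZT14 replicate 2 (adjusted p = 0.0411). Averaged over both times, dysc (3L 13867414–13903236), which takes part in clock output, was higher by 0.80 (SE 0.10, adjusted p = 0.00497), at 17.8 ± 1.59 and 34.4 ± 0.178 FPKM in wild type and 35.2 ± 5.84 and 54.4 ± 3.32 in vri679. On the same average to was higher by 1.12 (SE 0.18, adjusted p = 0.0106).

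**Figure D2:**
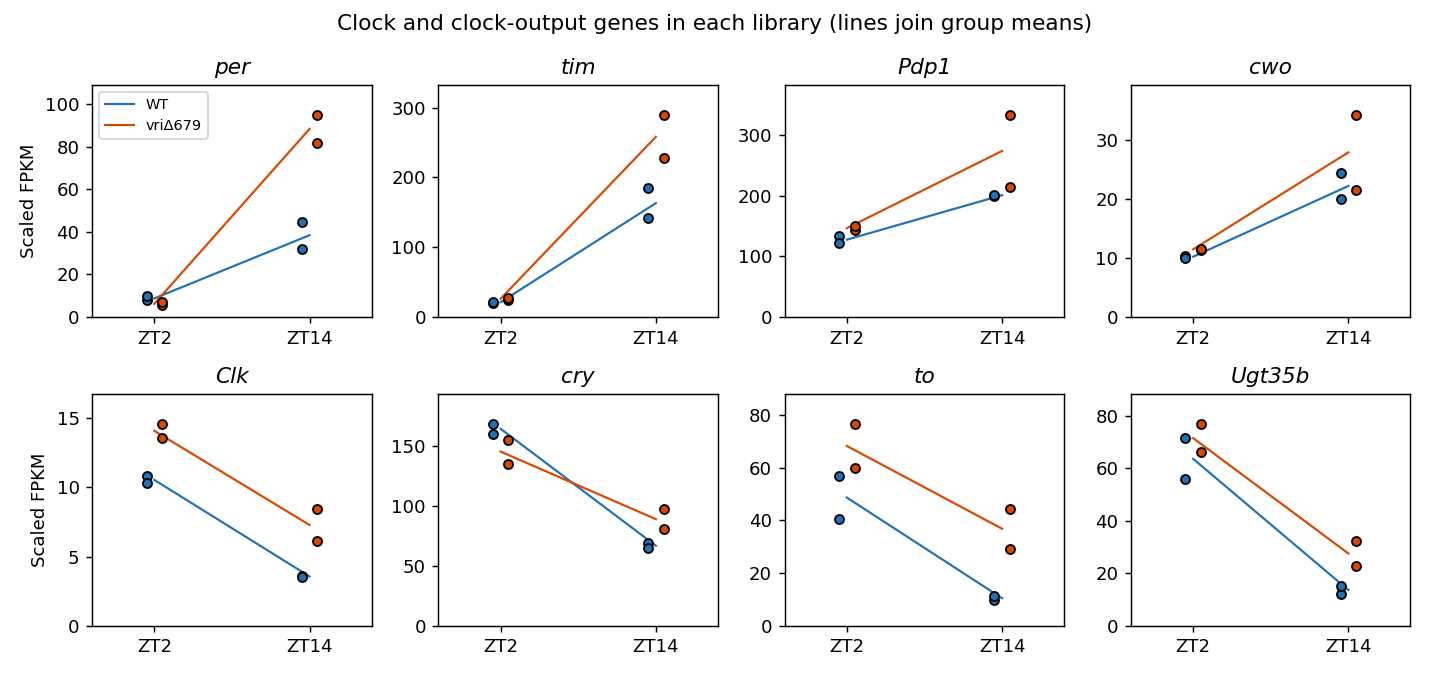
Scaled FPKM of 8 clock and output genes in each library at ZT2 and ZT14, with lines joining group means. Blue is wild type and orange is vri679.

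Genome-wide, the genotype comparison at ZT2 asked which head transcripts differ in the morning. CG8757 (3L 13840197–13842240) was higher in vri679 by 3.78 (SE 0.12, adjusted p = 3.11e-05), at 13.7 ± 0.781 against 0.535 ± 0.0567 FPKM, and CG10560 (3R 25318550–25320101) by 3.90 (SE 0.17, adjusted p = 0.000166), at 89.5 ± 8.32 against 5.56 ± 1.24. Mec2 (X 19188035–19190193) stood at 0.0236 and 0.108 FPKM in the wild-type and 9.65 and 7.97 in the vri679 libraries. CG5391 (3R 22333088–22334150) was lower by −5.94 (SE 0.19, adjusted p = 3.11e-05), at 35.9 ± 0.937 in wild type against 0.204 and 0.0 in the vri679 libraries, and CG17672 (3L 13028962–13036504) by −3.98 (SE 0.11, adjusted p = 3.11e-05). The cytochrome P450 gene Cyp309a2 (2L 2564886–2573037) was lower by −2.95 (SE 0.16, adjusted p = 0.000398) and the cuticle gene Cpr49Ac (2R 12386666–12390057) by −3.90 (SE 0.33, adjusted p = 0.00207). Exons of CG8757 and CG17672 overlap a noncoding gene. white (w), which encodes an eye pigment transporter, was lower by −2.70 (SE 0.27, adjusted p = 0.00372), at 3.18 ± 1.49 against 0.0421 ± 0.0118.

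Of 9 lists past the threshold at ZT2, only ribosomal protein and starvation response passed whichever library was left out. Ribosomal protein genes had a median of −0.37 with 0 of 80 called [0] (camera adjusted p = 3.34e-07; adjusted p = 0.878 with an estimated correlation). Starvation-response genes had a median of −0.44 with 4 of 13 lower [6], 0 without wild-type ZT2 replicate 1 or 2 or vri679 ZT2 replicate 2, and 2 without vri679 ZT2 replicate 1 or wild-type ZT14 replicate 1 or 2 (camera adjusted p = 0.00901; adjusted p = 0.69 with an estimated correlation). In all, limma called 292 genes, 190 higher and 102 lower, of 1455 with an unadjusted p under 0.05. The count was 104 and 94 without wild-type ZT2 replicates 1 and 2, and 141 and 112 without vri679 ZT2 replicates 1 and 2. It was 611 without vri679 ZT14 replicate 1 and 618 without the library labelled vri679 ZT14 replicate 2.

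At ZT14 the genotype comparison asked the same of the early night. CG8757 was higher by 4.51 (SE 0.12, adjusted p = 1.37e-05) and CG10560 by 4.12 (SE 0.17, adjusted p = 9.58e-05), and CG5391 was lower by −5.73 (SE 0.19, adjusted p = 2.4e-05), as at ZT2. Among secreted proteins, Lsp2 (3L 12129393–12131869), a larval serum protein also made by adult fat body, was lower by −5.58 (SE 0.53, adjusted p = 0.00149), at 5.19 ± 1.02 against 269 ± 20.8 FPKM. The odorant-binding gene Obp99b (3R 29716254–29716896) was lower by −5.16 (SE 0.48, adjusted p = 0.00137), at 17.8 ± 12.6 against 575 ± 75.7, and Fbp1 by −2.57 (SE 0.26, adjusted p = 0.00134). Pepck (2R 18536767–18539416), the gluconeogenic enzyme gene, was lower by −2.31 (SE 0.13, adjusted p = 0.000195), at 76.4 ± 8.28 against 380 ± 20.9. Exons of Lsp2 and CG8757 overlap an antisense gene.

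Neuropeptide and photoreceptor genes were among those higher at ZT14. Pdf (3R 26455462–26456141), made by clock neurons, was higher by 1.06 (SE 0.12, adjusted p = 0.00236), at 114 ± 11.3 against 54.5 ± 2.38 FPKM, and Dsk by 1.5 (SE 0.12, adjusted p = 0.000593), at 198 ± 2.42 against 69.4 ± 3.97. The insulin-like genes moved in opposite directions: Ilp2 was higher by 1.28 (SE 0.11, adjusted p = 0.000801) and Ilp5 lower by −1.70 (SE 0.15, adjusted p = 0.000919). The opsin genes Rh6 (3R 15483158–15484699) and Rh4 were higher by 1.08 (SE 0.14, adjusted p = 0.00397) and 1.13 (SE 0.14, adjusted p = 0.00321), Rh6 at 1240 ± 125 against 586 ± 33.6, but the phototransduction list as a whole did not pass (median 0.14, camera adjusted p = 0.18). The neuropeptide list had a median of 0.46, with 13 of 26 members higher [16] and 4 lower [4] (camera adjusted p = 0.000121; adjusted p = 0.36 with an estimated correlation). Without wild-type ZT14 replicates 1 and 2, 8 and 7 members were higher and 2 and 1 lower, and with only the groups compared 8 were higher and 1 lower.

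Of 14 lists past the threshold at ZT14, several were lower in vri679. Proteasome genes had a median of −1.10, with 29 of 36 lower [32], 14 without wild-type ZT14 replicate 2, and 1 higher [1], 0 without any wild-type or vri679 ZT2 library (camera adjusted p = 2.32e-11; adjusted p = 0.478 with an estimated correlation). Rpt3 (X 11125101–11126785) was lower by −1.69 (SE 0.17, adjusted p = 0.00134), at 52.4 ± 4.18 against 172 ± 37.4 FPKM. Cuticle protein genes had a median of −0.97, with 28 of 51 lower [31], 18 without wild-type ZT14 replicate 2, and 4 higher [4], 0 and 2 without wild-type ZT14 replicates 1 and 2 and 1 without vri679 ZT14 replicate 1 (camera adjusted p = 1.38e-06; adjusted p = 0.478 with an estimated correlation), and Cpr62Bc (3L 1840281–1842084) was lower by −2.95 (SE 0.15, adjusted p = 0.000192), at 63.3 ± 5.29 against 493 ± 64.3. Fat body genes had a median of −1.95, with 8 of 13 lower [10] (camera adjusted p = 4.98e-06, and 0.36 with an estimated correlation). The female-enriched list (Yp1, Yp2, Yp3 and fit, all also on the fat body list) had a median of −1.51, with 2 of 4 called lower (camera adjusted p = 0.0394). It was lost with an estimated correlation and did not hold whichever library was left out. Starvation-response genes had a median of −0.54 (camera adjusted p = 0.044; adjusted p = 0.478 with an estimated correlation), with 5 of 13 lower [7] and 0 higher [0]. That list was lost without wild-type ZT14 replicate 1 (0.101, 3 lower), wild-type ZT2 replicate 1 (0.0502) or 2 (0.0501), or the library labelled vri679 ZT14 replicate 2 (0.268, 3 higher), and 2 were lower without wild-type ZT14 replicate 2.

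Markers of muscle, hemocytes and glia stood lower at ZT14 too, whereas the neuron list did not pass (median 0.01, mean −0.07, camera direction higher, adjusted p = 0.805). Without the library labelled vri679 ZT14 replicate 2, the neuron list had a median of −0.19 with 9 of 20 lower and 3 higher, against 1 [1] and 1 [1] with all libraries, and still did not pass (adjusted p = 0.292). Without any wild-type or vri679 ZT2 library 0 were lower, and without either wild-type ZT14 library 0 were higher. Muscle genes had a median of −0.71, with 9 of 19 lower [13], 3 without wild-type ZT14 replicate 2, and 1 higher [2], 0 without any library except the one labelled vri679 ZT14 replicate 2 (camera adjusted p = 0.000567; adjusted p = 0.36 with an estimated correlation). Hemocyte genes had a median of −0.94, with 4 of 10 lower [6] (camera adjusted p = 0.0013; adjusted p = 0.478 with an estimated correlation). Glial genes had a median of −0.74, with 9 of 14 lower [12], 2 and 0 without wild-type ZT14 replicates 1 and 2 (camera adjusted p = 0.000306; adjusted p = 0.36 with an estimated correlation). Ribosomal protein genes had a median of 0.56, with 12 of 80 higher [0] (camera adjusted p = 8.7e-11; adjusted p = 0.607 with an estimated correlation). That count was 0 without either wild-type ZT14 library, 4 without either wild-type ZT2 library, 6 without either vri679 ZT2 library, and 73 without the library labelled vri679 ZT14 replicate 2. It was 23 with no rescaling, 33 with equal totals, 39 with quantile normalization, 27 in the voom fit, 20 with a replicate block, 5 with no filter and 1 with only the groups compared. That last setting left 17 proteasome, 4 muscle, 3 starvation-response and 1 glial gene lower, and 1 cuticle protein gene higher.

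Over all genes at ZT14, limma called 2260, 965 higher and 1295 lower, of 3931 with an unadjusted p under 0.05. Replicates of vri679 ZT14 differed most (chi-square per degree of freedom 293.9, against 74.9 to 94.2 in the other groups), whereas the fit gave all groups the same spread. With only the groups compared, 789 genes were called. The direction of the majority depended on scaling: 42.7 % were higher with the main scaling, 56.2 % (1428 against 1112) with no rescaling, 55.9 % (1422 against 1123) with quantile normalization, and 57.6 % in the voom fit. The count was 774 and 599 without wild-type ZT14 replicates 1 and 2, and 1411 and 1417 without wild-type ZT2 replicates 1 and 2. It was 5188 without the library labelled vri679 ZT14 replicate 2, which retained 2160 of the 2260.

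Averaged over both times, the genotype comparison asked which differences remained in the mean of the 2 times. CG8757 was higher by 4.14 (SE 0.08, adjusted p = 2.86e-06) and CG10560 by 4.01 (SE 0.12, adjusted p = 1.55e-05), while CG5391 was lower by −5.83 (SE 0.13, adjusted p = 3.23e-06), CG17672 by −3.86 (SE 0.08, adjusted p = 2.86e-06) and Cyp309a2 by −3.00 (SE 0.12, adjusted p = 4.14e-05). Pepck was lower by −1.64 (SE 0.09, adjusted p = 0.000223). The glutathione S-transferase gene GstZ2 was higher by 0.86 (SE 0.08, adjusted p = 0.00207). In all 1424 genes were called, 594 higher and 830 lower, of 3165 with an unadjusted p under 0.05. The share higher was 41.7 %, against 60.4 % (1013 against 663) with no rescaling, 56.1 % (869 against 680) after rescaling to equal totals and 60.3 % in the voom fit. Every library left out moved the count: 638 and 493 (wild-type ZT14 replicates 1 and 2), 520 and 512 (wild-type ZT2), 729 and 643 (vri679 ZT2), 2200 (vri679 ZT14 replicate 1) and 4097 (the library labelled vri679 ZT14 replicate 2).

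As for whole lists on this average, which mixes times that can differ in sign, 15 passed with camera, and all 15 were lost with an estimated correlation (adjusted p = 0.391 to 0.847 with an estimated correlation). Lists with lower members were proteasome (median −0.62, adjusted p = 4.48e-10), glia (−0.39, 0.000161), cuticle protein (−0.38, 0.000377), hemocyte (−0.68, 0.00103), starvation response (−0.34, 0.0018), ecdysone (−0.25, 0.00262), muscle (−0.38, 0.00308) and lipid metabolism (−0.20, 0.00753). Lists with higher members were glutathione S-transferase (0.28, 0.000127), neuropeptide (0.18, 0.0018), clock output (0.58, 0.00309) and male-enriched (0.48, 0.0048). At ZT2 alone, cuticle protein had a median of 0.22 (camera adjusted p = 0.0172), a call that did not hold without vri679 ZT2 replicate 2. Its camera adjusted p was 0.0537 to 0.573 with equal totals, no rescaling, no filter or voom, and 0.878 with an estimated correlation. Also at ZT2, fat body had a median of 0.17 (camera adjusted p = 0.166), neuropeptide −0.15 (0.173), muscle 0.06 (0.736) and ribosomal protein −0.37. Each of these ZT2 medians was opposite in sign to the average. Heat shock (−0.40, 0.006) and fat body (−0.51, 0.00309) were each at adjusted p = 0.0612 without the library labelled vri679 ZT14 replicate 2. Ribosomal protein (0.11, 0.00981) was at 0.667 without vri679 ZT14 replicate 1 and at 0.173 without vri679 ZT2 replicate 1.

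The other 15 lists tested did not pass on this average. Medians with camera adjusted p were −0.15 (0.0893) for eye pigment, 0.22 (0.102) for odorant binding, −0.69 (0.145) for female-enriched and −0.13 (0.179) for the dpp pathway. They were −0.38 (0.245) for antimicrobial immunity, 0.35 (0.245) for Turandot stress and 0.31 (0.337) for the evening clock, vri included. UDP-glycosyltransferases stood at 0.09 (0.353) and phototransduction at 0.02 (0.454). Sugar digestion stood at −0.31 (0.609), the other core clock genes at −0.07 (0.674), neuron at 0.04 (0.674), immediate early activity at −0.02 (0.692), oxidative phosphorylation at −0.03 (0.692) and cytochrome P450 at 0.08 (0.713). For neuron and cytochrome P450 the means were −0.01 and −0.10, opposite in sign to the median and to the camera direction. Some of these passed with a library left out. Without wild-type ZT2 replicate 1, odorant binding passed (adjusted p = 0.0311), and so did female-enriched without wild-type ZT2 replicate 2 (0.0229) or wild-type ZT14 replicate 2 (0.0376). Antimicrobial immunity passed without vri679 ZT14 replicate 1 (0.0152) or vri679 ZT2 replicate 2 (0.000476). Oxidative phosphorylation passed in opposite directions, lower without vri679 ZT14 replicate 1 (median −0.18, 0.000661) and higher without the library labelled vri679 ZT14 replicate 2 (median 0.11, 0.0321), and odorant binding and the dpp pathway passed without the latter (0.02 each). Of lists too small to test, the morning clock pair Clk and cry differed by 0.66 and 0.11, and Cp18, the single gene tested for body parts outside the head, by 0.15; no mitochondrially encoded gene was listed.

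**Figure D3:**
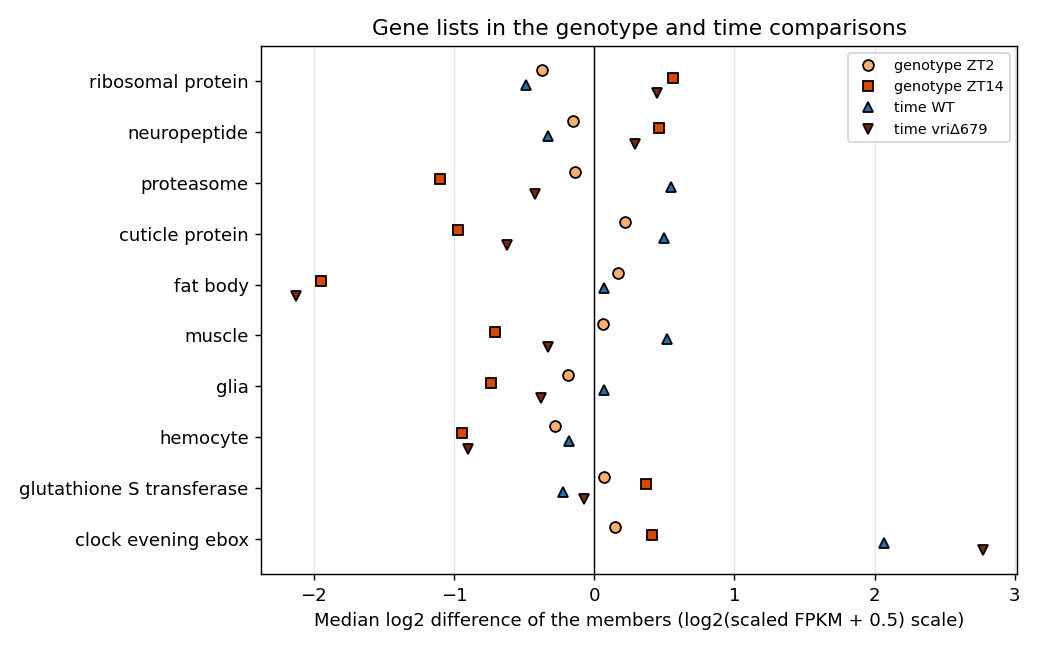
Median log2 difference of the members of 10 gene lists in the 2 genotype comparisons and the 2 time comparisons.

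Beyond the clock, the comparison of ZT14 with ZT2 in wild type asked which transcripts differ between morning and early night. CG14118 rose by 4.79 (SE 0.16, adjusted p = 6.58e-05), from 0.217 ± 0.0383 to 19.5 ± 3.58 FPKM, and the muscle gene Zasp67 by 3.51 (SE 0.22, adjusted p = 0.000446). Cuticle genes moved both ways: Cpr62Bc rose by 2.56 (SE 0.15, adjusted p = 0.000446), whereas Cpr49Ac fell by 3.90 (SE 0.33, adjusted p = 0.00144) and Cpr66D by 1.91 (SE 0.13, adjusted p = 0.000538). The cuticle list had a median of 0.50 with 19 of 51 up [22] and 4 down [5] (camera adjusted p = 1.59e-07; adjusted p = 0.733 with an estimated correlation). Without wild-type ZT2 replicate 1 or 2 or wild-type ZT14 replicate 2, 9 were up, and without any of the 4 wild-type libraries 2 were down. All 80 ribosomal protein genes stood lower at ZT14, with a median of −0.49 and 0 called [0], 36 without vri679 ZT14 replicate 1, 34 without the library labelled vri679 ZT14 replicate 2 and 68 with only the groups compared (camera adjusted p = 9.59e-14; adjusted p = 0.814 with an estimated correlation). Limma called 671 genes in wild type, 396 up and 275 down, of 2025 with an unadjusted p under 0.05. The count was 297 and 163 without wild-type ZT14 replicates 1 and 2, 148 and 169 without wild-type ZT2 replicates 1 and 2, 1442 without vri679 ZT14 replicate 1 and 1433 without the library labelled vri679 ZT14 replicate 2.

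Within vri679 the same question was asked. cyr (X 8121280–8135713) rose by 3.07 (SE 0.12, adjusted p = 0.000173), from 1.11 ± 0.00648 to 13.1 ± 0.284 FPKM. Jhedup, which encodes a carboxylesterase, fell by 4.69 (SE 0.27, adjusted p = 0.000479), GstE4 by 4.47 (SE 0.33, adjusted p = 0.00119), from 57.8 ± 8.65 to 2.28 ± 1.30, and the female-biased gene fit by 3.92 (SE 0.33, adjusted p = 0.0018). Os-C fell by 6.63 (SE 0.59, adjusted p = 0.00331) and Obp69a by 4.03 (SE 0.30, adjusted p = 0.00119). The odorant-binding list had a median of −0.33 with 8 of 32 down [9] and 0 up [2] (camera adjusted p = 0.00807; adjusted p = 0.779 with an estimated correlation), but 8 down and 8 up without the library labelled vri679 ZT14 replicate 2 (camera adjusted p = 0.642). The fat body list fell with a median of −2.13, with 10 of 13 called [13], 5 and 6 without vri679 ZT2 replicates 1 and 2 and 6 with only the groups compared (camera adjusted p = 1.14e-08; adjusted p = 0.396 with an estimated correlation). Beside it stood the female-enriched (genes also on the fat body list, median −2.26, camera adjusted p = 0.00195), hemocyte (−0.90, 0.00195), glia (−0.38, 0.00807) and muscle (−0.33, 0.00963) lists. Each was at adjusted p = 0.492 with an estimated correlation. Without the library labelled vri679 ZT14 replicate 2, the first 3 were at 0.0912 and muscle at 0.173. Limma called 1009 genes in vri679, 363 up and 646 down, of 3142 with an unadjusted p under 0.05. The share up was 36 %, against 55.8 % (722 against 571) with quantile normalization. With only the groups compared, 183 genes were called. The count was 526 without wild-type ZT14 replicate 1 or 2, 503 and 508 without wild-type ZT2 replicates 1 and 2, 289 and 262 without vri679 ZT2 replicates 1 and 2, and 4613 without the library labelled vri679 ZT14 replicate 2.

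Genotype by time asked whether the time difference itself depended on genotype. per had a larger time difference in vri679, by 1.67 (SE 0.29, adjusted p = 0.0183), a call lost without wild-type ZT2 replicate 2 (1.52, adjusted p = 0.082), wild-type ZT14 replicate 2 (1.44, adjusted p = 0.0679) or vri679 ZT2 replicate 1 (1.53, adjusted p = 0.0676). Pdf stood at 81.2 ± 2.09 and then 54.5 ± 2.38 FPKM in wild type, and at 60.2 ± 4.63 and then 114 ± 11.3 in vri679, a difference of 1.49 (SE 0.17, adjusted p = 0.00498). Dsk differed by 1.68 (SE 0.17, adjusted p = 0.00315), NPF by 1.21 (SE 0.14, adjusted p = 0.00527), and Ilp5 by −2.43 (SE 0.21, adjusted p = 0.00209). Lsp2 stood at 28.9 ± 7.78 and then 269 ± 20.8 in wild type, and at 168 ± 127 and then 5.19 ± 1.02 in vri679, a difference of −7.88 (SE 0.74, adjusted p = 0.00318). Limma called 835 genes, 240 positive and 595 negative, of 2732 with an unadjusted p under 0.05, a share of 28.7 % positive against 45.0 % (463 against 566) with quantile normalization. The count was 394 and 258 without wild-type ZT14 replicates 1 and 2, 308 and 255 without wild-type ZT2 replicates 1 and 2, 382 and 323 without vri679 ZT2 replicates 1 and 2, 1291 without vri679 ZT14 replicate 1 and 4197 without the library labelled vri679 ZT14 replicate 2.

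The last question was how far effects were shared between comparisons whose differences use no library in common. All came from the same fit with a shared spread per gene, so calls of a gene in both comparisons are not independent. The counts for independent calls below are therefore a reference and not a test. Across genes, the genotype difference at ZT2 correlated with that at ZT14 at r = 0.14. Among called genes, 58 were higher in vri679 at both times, where independent calls would give 18.1, and 49 were lower at both, where they would give 13. In opposite directions, 34 were higher at ZT2 and lower at ZT14 (24.3 if independent) and 9 lower at ZT2 and higher at ZT14 (9.7). The time difference in wild type correlated with that in vri679 at r = 0.04, with 44 genes up in both (14.2 if independent), 76 down in both (17.6), 99 up in wild type and down in vri679 (25.3) and 17 the other way (9.9).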

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

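All tests of explanations in this part except those on receptor genes were written after the pattern was seen, and the lists of receptor genes were added after the data were seen but before their own values were. The differences listed first were flagged because a planned test of genotype by time found the time difference to depend on genotype.

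Genotype by time called 835 genes. Among the evening, morning and output clock genes only per passed, at 1.67. Of the other core clock genes, Pdf passed at 1.49, and Atx2 at −1.44, a call lost without any wild-type or vri679 ZT2 library (adjusted p = 0.079 to 0.112). Positive differences, with a time difference higher in vri679, were largest for CG17327 (6.93), CG9757 (3.62), CG5773 (3.48), CG13931 (3.33), CR44138 (3.11), DnaJ-60 (3.09), CRG (3.05) and Sirt4 (2.89). Negative ones were largest for Lsp2 (−7.88), CG44194 (−5.79), Fbp2 (−5.61), tobi (−5.32), Fbp1 (−4.62), CG4017 (−4.31), fit (−4.29) and CG13063 (−4.26). The call of CG9757 was lost without wild-type ZT2 replicate 1 (adjusted p = 0.0508) or wild-type ZT14 replicate 2 (0.0579), and that of tobi without wild-type ZT2 replicate 2 (0.0574) or wild-type ZT14 replicate 2 (0.0524). The call of Sirt4 was lost without any of the 4 wild-type libraries or vri679 ZT14 replicate 1 (0.0572 to 0.0899). The per call was lost without wild-type ZT2 replicate 2 (0.082), wild-type ZT14 replicate 2 (0.0679) or vri679 ZT2 replicate 1 (0.0676). CG17327 and CG44194 have identical coordinates, so the division of reads between them is uncertain. In the wild-type ZT14 libraries CG17327 stood at 0.0 FPKM and CG44194 at 29.7 and 31.7. In all other libraries CG17327 stood at 37.7 to 81.5 and CG44194 at 0.00919 to 0.0729. Their differences therefore reflect mainly which symbol the reads were assigned to, not a change of either gene. DnaJ-60, CRG, Lsp2 and Sirt4 overlap exons of another gene.

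Among lists, the median difference of differences was −1.12 for cuticle protein (camera adjusted p = 8.6e-08), −2.40 for fat body (3.63e-06), −0.49 for glia (0.0484), −0.73 for muscle (0.00148), 0.57 for neuropeptide (1.63e-05), −1.04 for proteasome (5.28e-10) and 0.93 for ribosomal protein (9.19e-17). All were lost with an estimated correlation (adjusted p = 0.342 to 0.624 with an estimated correlation). Glia was also lost without wild-type ZT14 replicate 1 (0.0543) or 2 (0.0526), wild-type ZT2 replicate 2 (0.131), vri679 ZT2 replicate 1 (0.0674) or the library labelled vri679 ZT14 replicate 2 (0.104).

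The first pattern weighed was the long vri form at 30.1 FPKM in the library labelled vri679 ZT14 replicate 2. A whole library of this study's wild type was excluded, since w stood at 0.0819 FPKM there and above 2 in each wild-type library. Part of the RNA from this study's wild type was excluded too: 6 genes on in wild type and near 0 in the other vri679 libraries stood at a median fraction of 0.002 of the wild-type level (−0.004 to 0.009), where 0.389 was needed. A first form of that test, with a ceiling of 0.2 FPKM, had used 3 genes and given 0.007 (−0.001 to 0.009). An intact vri allele from a stock other than this study's wild type remains open, because the rule written for it could not be met. It asked for a short-form ratio below the lowest between replicates of the other groups, 0.0984, but also above a bound higher than that. The short form stood at 0.486 of its level in vri679 ZT14 replicate 1. Between replicates of the other groups the ratio ran from 0.0984 to 0.848. The lowest was in wild-type ZT2, with short vri at 0.451 and 0.0444 FPKM, and the highest in vri679 ZT2. A first form of the test had set the ratio against that of the long form in wild type (0.868 and 0.903).

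The second pattern was antennal genes that stood highest at vri679 ZT2 and lower at ZT14 in both genotypes, such as Os-C at 118 and 88.5 FPKM in vri679 ZT2 and 1.44 and 0.0536 in vri679 ZT14. If antennal tissue differed between groups, receptor genes of antennal neurons were to fall by 1 or more. Their median time difference was −0.44 in wild type and −0.62 in vri679, which met neither the value set for it nor the one set against it, so unequal antennal tissue remains open. Between genotypes at ZT2 antennal receptor genes had a median of 1.39, with 11 of 14 higher in vri679. Palp receptor genes had one of 1.32, so neither tissue share nor expression is ruled out there. Palp receptor genes, of which 4 could be used, had medians of −0.04 and −1.93, so a change across olfactory organs remains open as well.

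The third pattern was fat body genes lower at vri679 ZT14, with a list median of −1.95. A lower share of fat body as the whole cause was to make the 13 members fall alike, but 6 of 13 differed from the median by over 3 SE. Members ranged from −5.58 (Lsp2) to −0.33 (Rfabg). Equal falls follow only if every member is made in fat body alone, which was not tested. This cause therefore remains open. Starvation remains open: the 5 starvation-induced genes tested had a median of −0.51 but went both ways. By sign alone, called or not, 2 were higher and 3 lower, with quartiles of −0.68 and 0.13. Pepck, listed under an older symbol and so left out of the 5, was lower by −2.31. Against starvation, the starvation-response list fixed beforehand had a median of −0.54 (camera adjusted p = 0.044). Of its 13 members 5 were called lower and 0 called higher, counts of calls that do not compare with the counts by sign. Its median was −0.44 without the library labelled vri679 ZT14 replicate 2, and its camera call did not hold whichever library was left out. Fewer females could not account for Lsp2 and Obp99b, which lay at least 3.46 below the lowest yolk-protein gene. For the other members fewer females remain possible, since male-specific roX2 differed by 0.26 (SE 0.29, adjusted p = 0.534) and was uninformative. A first form of this test had been met (4 of 4 roX1 and roX2 values above both wild-type ZT14 libraries), and a second asked for 3 members below the yolk-protein genes and found 2. The female-enriched list was at a median of −1.51 (camera adjusted p = 0.0394). Its genes, Yp1, Yp2, Yp3 and fit, are also members of the fat body list. It is therefore no separate observation and cannot tell fewer females from less fat body.

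Regrouping the libraries was tested by all 35 splits into 4 and 4 in a 2-group fit. Only 1 split reached as many calls as genotype, namely the genotype split itself with 139, and the next highest, the split by time, reached 77. Every other split put both genotypes on each side, so genotype differences entered its spread and lowered its count. These splits therefore cannot tell how many calls of the 4-group fit arose by chance.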

How the results depend on the processing

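The voom fit, vri by first exon and the list counts without each vri679 ZT14 library were chosen after the data were seen; the other settings were fixed beforehand. Over all settings, named genes kept direction and side of the threshold in 8164 comparisons, lost the call in 1293, gained it in 37 and reversed in 33. For vri by first exon these counts were 182, 10, 13 and 7. For lists they were 1292, 205, 0 and 3, but only lists past the threshold in the main fit were counted, so none could gain a call. Lists that passed only in another setting, such as odorant binding on average, are not among them. Of named genes called, 16 of 41 (genotype ZT2), 59 of 105 (genotype ZT14), 52 of 94 (average), 23 of 76 (time in wild type), 28 of 82 (time in vri679) and 26 of 67 (genotype by time) were called in every setting. With 2 libraries per group, spread between replicates rather than depth limited the calls, and the cause of the changes below was not tested unless stated.

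With one library left out, genes called ranged over 94 to 618 (genotype ZT2), 599 to 5188 (genotype ZT14), 493 to 4097 (average), 148 to 1442 (time in wild type), 262 to 4613 (time in vri679) and 255 to 4197 (genotype by time). With transcripts as features, over more tests, the counts were 123, 781, 501, 185, 382 and 313 in that order. A filter at FPKM 5 gave 172 at genotype ZT2, with fewer genes tested. With only the groups compared, genotype ZT2 had 435, genotype ZT14 789, time in wild type 1567 and time in vri679 183. Against the main fit, counts fell where vri679 ZT14, the group with the largest spread between replicates, was compared. They rose where it was not, so fewer libraries alone do not account for the changes. Lists past the threshold were 9, 14, 15, 14, 16 and 7, but 0 in every comparison with an estimated correlation. Fry gave 0 at genotype ZT2, 3 for time in wild type and 8 for time in vri679. With one library left out, lists ranged over 3 to 13, 11 to 15, 14 to 16, 10 to 15, 4 to 18 and 6 to 12.

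For vri-RD at ZT2, main −4.20, the call was lost after rescaling to equal totals (−4.98, adjusted p = 0.0626), with a pseudocount of 0.1 (−6.46, 0.111) and at FPKM 5 (−4.20, 0.0711), and for vri-RD at ZT14 with only the groups compared (−6.13, 0.0841). With one library left out, vri-RD ranged over −4.26 to −4.15 at ZT2 and −6.87 to −5.39 at ZT14, and vri-RE over 2.22 to 3.03 and 2.13 to 3.69.

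Long vri in genotype by time, main 0.32 (SE 2.34, adjusted p = 0.959), passed in opposite directions without either vri679 ZT14 library: 3.02 (SE 0.19, adjusted p = 0.0121) without replicate 1 and −2.39 (SE 0.22, adjusted p = 0.0123) without the library labelled replicate 2. The latter sign rests on the pseudocount of 0.5, above the vri679 levels left (0.0183, 0.0118 and 0.218 FPKM), so it says nothing of the ratio of levels. Other values changed sign with one library left out, without passing the threshold on the changed side, over these ranges. At genotype ZT2: Ih −0.01 to 0.13, Ugt35b 0.0 to 0.35, na −0.09 to 0.31. At genotype ZT14: cwo −0.03 to 0.62, na −0.51 to 0.2. On average: na −0.2 to 0.16. For time in wild type: Ih −0.08 to 0.07, na −0.12 to 0.07. For time in vri679: Cyp6a21 −0.35 to 0.12, Ih −0.02 to 0.15, na −0.65 to 0.07. For genotype by time: short vri −0.49 to 1.07, vri −0.54 to 0.34, Pdp1 −0.11 to 0.52, cwo −0.18 to 0.47, Ih −0.01 to 0.16, na −0.63 to 0.09. Camera adjusted p of lists that reversed ranged over 2.05e-08 to 0.667 (ribosomal protein, average), 1.07e-08 to 0.832 (antimicrobial immunity, time in vri679) and 8.08e-08 to 0.215 (oxidative phosphorylation, time in vri679).

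Other settings reversed na on average (0.05 with no rescaling and in the voom fit, 0.01 with equal totals, 0.02 with quantile normalization), Ih in wild type over time (0.04 with equal totals, 0.03 in the voom fit), and, with equal totals, na in wild type (0.02) and Ih in vri679 (−0.01) over time. In genotype by time they reversed Ih (−0.06 with equal totals), vri (0.05 with quantile normalization), long vri (−0.21 with a pseudocount of 1) and short vri (−0.14 with equal totals, −0.59 with a pseudocount of 0.1).

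As a block, replicate numbers, which nothing in the labels makes a pairing, gave 322, 2263, 1440, 733, 1033 and 860 genes called, and −4.20 (adjusted p = 0.0813) for vri-RD at ZT2. Deviations of same-numbered libraries correlated at −0.14 to 0.27.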

Other observations

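None of the values in this part rests on a test chosen after the data were seen. The wild-type label gives the strain w1118, yet white (w) stood at 2.12, 4.23, 5.99 and 5.25 FPKM in the 4 wild-type libraries and at 0.0338, 0.0504, 0.0338 and 0.0819 in the vri679 libraries, in the order ZT2 replicates 1 and 2, ZT14 replicates 1 and 2.

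Sex-biased transcripts varied between replicates. In the same order of libraries, the yolk-protein gene Yp1 stood at 5600, 3410, 2850 and 1260 FPKM in wild type and 3960, 2690, 1350 and 882 in vri679. The male-specific noncoding gene roX1 stood at 16.7, 52.2, 27.9 and 35.9 in wild type and 49.3, 62.0, 196 and 42.6 in vri679, and roX2 at 14.9, 29.7, 18.9 and 16.0, then 33.3, 29.4, 20 and 21.9.

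Antennal genes differed widely in level between groups. Obp83a stood at 14.4, 9.85, 0.478 and 0.46 FPKM in wild type and 194, 120, 7.26 and 0.591 in vri679, and a10 at 12.4, 10.4, 0.523 and 0.533, then 188, 121, 7.49 and 0.511. The olfactory co-receptor gene Orco stood at 4.06, 3.58, 3.1 and 2.42, then 24.9, 16.4, 2.98 and 2.51.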
